A study of Ptychodera flava with 36 samples.

How the data were processed

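RNA was taken from the posterior piece of bisected adult Ptychodera flava at 9 times from 0 h to 96 h, per the labels, with 3 to 5 libraries at each time. Per the labels' protocols, worms were kept at 1 of 2 sites while regenerating, RNA was isolated with 1 of 2 spin-column kits, and libraries were made with the TruSeq Stranded mRNA kit. The labels do not say which site or kit each sample had. The design text speaks of 4 reference animals and at least 4 replicates at each time; the samples analysed here include 3 at 0 h and 3 at 4 h. Per the submitters' processing notes, Bowtie2, SAMtools and DESeq2 were used; their versions and roles are not given in the sources used here. The assembler, the assembly, the counting tool and its strand setting are likewise not given in the sources used here.

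The deposited count table holds raw whole-number counts for 246590 assembled components in 36 columns, per the file headers, and the unit was checked on the values. Of these components, 3663 had no count in any library. A second table holds the authors' comparisons of each time with 0 h, per the file headers. The authors' log2 fold change and the authors' adjusted p-value of each component were taken from it. The sign of the deposited log2 fold changes was checked against the counts and is positive where the later time is higher. Component numbers were looked up in the reference table of gene names and accessions, and 0 matched, so no gene names were used. The gene lists drawn up for the tissue, and the parts of the naming rule that need gene names, were therefore not run. Because contigs of an assembly can split a gene, or part its alleles and near-identical copies, a component is not necessarily a gene, and reads that could belong to several components leave their counts uncertain.

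Library totals ranged from 5520886 to 9388318 counts. Intervals and floors cover counting error only, since reads were counted without molecular identifiers. The share of the most abundant component in 96 h replicate 4 had an exact 95% binomial interval from 34.81% to 34.87%. A count of 0 was given a floor of 3 counts over the libraries of the group. No columns of the count table were identical, and no pair of libraries of a time agreed within counting noise, so each library was counted as 1 sample. This does not show that they came from separate worms, since repeat preparations of a worm would also differ by more than counting noise. In 3 pairs the chi-square per degree of freedom was far lower than in the other 53, where it ran from 19.02 to 96.43: 6.07 for 6 h replicates 3 and 4 (Spearman correlation 0.955), 7.44 for 2 h replicates 1 and 2 (0.956) and 9.8 for 96 h replicates 1 and 2 (0.967). Pairs from different times were not compared by chi-square. By Spearman correlation, 4 h replicate 2 with 2 h replicate 1 (0.9545) and 6 h replicate 1 with 4 h replicate 2 (0.9542) were nearly as close. Replicate numbers are those of the titles; the sample names number the 0 h libraries 1, 3 and 4 where the titles have 1, 2 and 3.

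The analysis used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0. Components were filtered with edgeR's filterByExpr by time group (minimum count 10, minimum total 15), which left 43271. Library sizes were scaled by TMM, with factors from 0.779 to 1.31. All 36 libraries were fitted in a single quasi-likelihood model with time group as the only factor (estimateDisp, glmQLFit, glmQLFTest), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The joint test took 8 coefficients together, each time was compared with 0 h, and the mean of 48, 72 and 96 h was compared with that of 2, 4 and 6 h. The standard error of a fold change was its size divided by the square root of F. Where a group has no counts, as for the named components at their named times, this value does not measure the precision of the fold change. The biological coefficient of variation was 0.564 over the 36 libraries and 0.412 in the larger set. CPM values used TMM-scaled library sizes, and log2 CPM used a prior count of 2.

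The rule for named components was written before the data were examined. It took strong changes with an informative gene name at each time and in each gene list, and, where the files pair no names with component numbers, the 2 largest rises and 2 largest falls over the joint test. The last part was the one that could be used. The design, the main test and most of the other settings were likewise set before the data were examined.

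Libraries were clustered by average linkage on 1 minus the Spearman correlation of log2 CPM and parted into 2 sets. The sets were found in the data and are not the study's groups. The correlation of each library with the 0 h libraries was related to time within each set by permutation tests with 100000 resamples. Shared-control overlap was compared with independent lists and with 8 simulations of unchanged groups, which were also run for the larger set alone and with the set as a term.

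The edgeR step was tested on simulated counts for the 43271 components with known changes. Each component was drawn on its own, without a difference between the sets. At 96 h it recovered 38.5% of components changed 8-fold, 20.3% of those changed 4-fold and 0% of those changed 2-fold. At 48 h it recovered 64.7%, 27.8% and 5%. Between 0 and 2 unchanged components were called in each simulated comparison.

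Other settings, chosen beforehand, were DESeq2 size factors (RLE) in edgeR, DESeq2, limma voom with sample quality weights, no filter on low counts, a stricter filter (CPM of at least 1 in 9 libraries), a minimum log2 fold change of 1, only both groups of a comparison in the fit, the replicate number of the titles or of the sample names as a block, components summed by number, and each library left out in turn. The larger set alone, the set as a term and the 3 close pairs summed and taken as 1 library each were added after the data were seen. Other splits of the samples were counted for each comparison. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.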

Results

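Ptychodera flava is an acorn worm, a hemichordate that lives in marine sediment and can regrow lost body parts after a cut. The series followed gene expression in the posterior piece of adult worms after a cut across the trunk near the front hepatic sacs, the pouches of the gut that mark the middle of the body. Poly(A) RNA was sequenced at 2, 4, 6, 12, 24, 48, 72 and 96 h after the cut, and tissue taken at once after bisection (0 h) was the reference. The 36 libraries comprised 3 at 0 h, 4 at 2 h, 3 at 4 h, 4 at 6 h, 4 at 12 h, 5 at 24 h, 5 at 48 h, 4 at 72 h and 4 at 96 h. Expression was given as raw read counts of 246590 components, which are groups of transcripts assembled from the reads, each with a number and no gene name. The total count per library ranged from 5520886 to 9388318 with a median of 6966775, and between 70207 and 100302 components had at least 1 count in a library. After removal of low counts, 43271 components were tested, and these held between 97.9% and 99.1% of the counts of each library. The component comp288419_c0, singled out after its values were seen because it was the most abundant, held 7.64% ± 1.64 of all counts at 0 h (SD, n = 3) and 18.8% ± 11.6 at 96 h (SD, n = 4). In 96 h replicate 4 its share was 34.8%. It did not pass the test over all times (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0592).

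The libraries fell into 2 sets that did not follow time alone. Average-linkage clustering of Spearman correlations put 23 libraries in a larger set and 13 in a smaller set. The larger set held all 3 libraries at 0 h and all 4 at 6 h, and the smaller set held all 4 libraries at 96 h. The other members of the smaller set were 2 h replicate 4, 4 h replicate 3, 12 h replicate 4, 24 h replicates 1 and 4, 48 h replicates 1 and 3, and 72 h replicates 1 and 2. The median Spearman correlation was 0.865 within the larger set, 0.803 within the smaller set and 0.754 between the sets. The smaller set was the looser, and at 48 h its replicates 1 and 3 correlated at 0.785, below the 0.793 to 0.822 of replicate 1 with the larger-set libraries of that time. The first principal component, with 26.6% of the variance, ran from -137 to -7.46 in the larger set and from 50.8 to 162 in the smaller set. The protocols name 2 holding sites and 2 RNA extraction kits without assigning them to samples, so neither could be compared with the sets. The counts of changed components are therefore given also for the 23 libraries of the larger set and with the set as a term in the model, both chosen after the data were seen. The 96 h group has no library in the larger set, and the smaller set has none at 0 h.

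**Figure D1:**
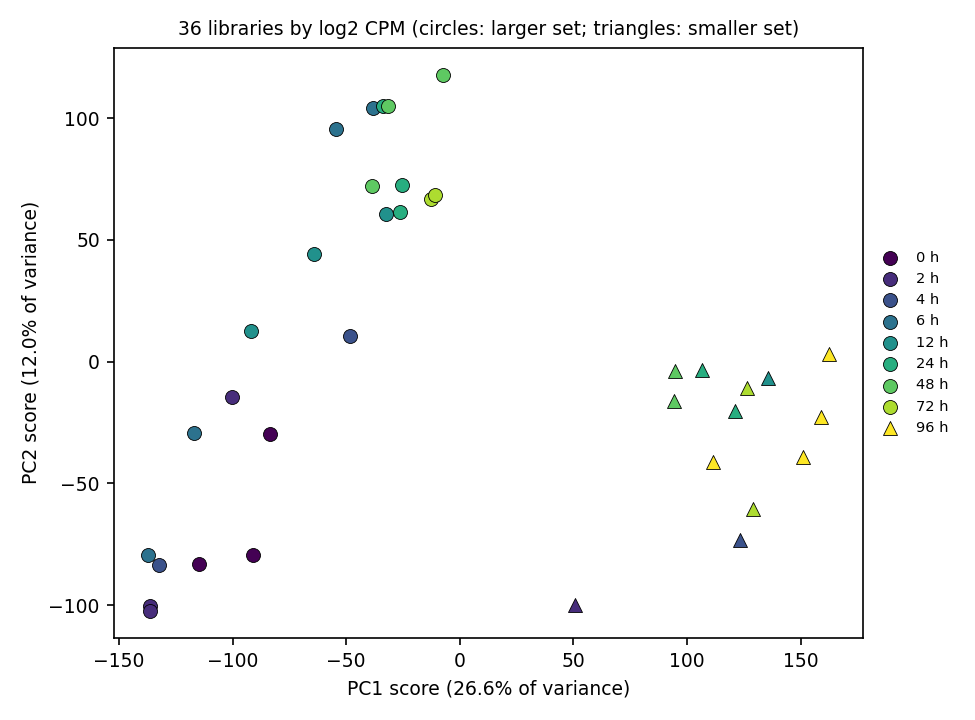
Principal component scores of the 36 libraries from log2 CPM, with colour for time after bisection, circles for the 23 libraries of the larger set and triangles for the 13 of the smaller set. The horizontal axis (26.6% of the variance) separates the sets, and all 4 libraries at 96 h lie on the side of the smaller set.

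Over the whole course, 10237 of the 43271 components, or 23.7%, differed between at least some times (edgeR quasi-likelihood test of 8 coefficients jointly, Benjamini-Hochberg adjusted p under 0.05). Of these, 5906 also passed the test at 1 or more single times against 0 h and 4331 passed only jointly. Single comparisons with 0 h called 8028 components at 1 or more times, of which 4700 were called at exactly 1 time and 3328 at 2 or more. These comparisons share the 3 libraries at 0 h, so calls at several times are not independent of each other. The larger set alone gave 4959 components over its 8 groups, of which 3987 were among the 10237, and the fit with the set as a term gave 8126. The labels do not say whether each library came from a separate worm, so the p-values measure the spread between these samples. In 3 pairs, 2 h replicates 1 and 2, 6 h replicates 3 and 4 and 96 h replicates 1 and 2, the libraries were far closer to each other than in the other pairs of a time, and with each pair summed and taken as 1 library, a setting chosen after the data were seen, 6317 components passed the joint test.

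The first comparisons asked which transcripts responded within hours of the cut. No component passed the threshold at 2 h or at 4 h by edgeR's quasi-likelihood test after the filter on low counts, in all 36 libraries or in the larger set alone, and with the set as a term there was 1 at 2 h and 0 at 4 h. With only both groups of a comparison in the fit, edgeR called 3 components at 2 h. At an unadjusted p under 0.05 there were 3457 components at 2 h and 3013 at 4 h, where 2164 would be reached by chance. DESeq2 on the same counts called 226 components at 2 h, of which 60 were higher, and 166 at 4 h, of which 114 were higher. With limma voom and sample quality weights the counts were 1355 and 419, and without a filter on low counts edgeR called 1463 and 1133. The authors' deposited table lists 156 components below an adjusted p of 0.05 at 2 h and 20 at 4 h. Simulated data of the same design held no sets, with each component drawn on its own. In them, edgeR recovered 54.7% of components changed 8-fold at 2 h and 49.3% at 4 h. For components changed 2-fold, edgeR recovered 2.63% at 2 h and 0% at 4 h. Without 0 h replicate 1 it called 24 components at 2 h and 42 at 4 h, without 0 h replicate 3 it called 9 at 2 h, and without 4 h replicate 2 it called 2 at 2 h and 6 at 4 h. At 4 h, leaving out 6 h replicate 1, 48 h replicate 1, 48 h replicate 3, 72 h replicate 1 or 72 h replicate 4 gave 1 component each.

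At 6 h, 385 components were higher and 452 lower than at 0 h. The higher components had a median log2 fold change of 1.88 (median SE 0.44), and together they took 2.68% ± 0.836 of all counts at 6 h (SD, n = 4) against 0.741% ± 0.0483 at 0 h (SD, n = 3). The lower components had a median log2 fold change of -2.31 (median SE 0.54), and their share was 0.377% ± 0.0526 at 6 h against 2.13% ± 0.765 at 0 h. Changes of 4-fold or more made up 431 of the 837 calls, and 5 of the called components had no count in any 0 h library. The components were chosen by the test on these same libraries, so the shares describe the calls and are no separate evidence. In the larger set alone, 1789 components were called at 6 h, including 776 of the 837, and the set as a term gave 1280. All 3 libraries at 0 h and all 4 at 6 h are in the larger set, so both settings compare the same libraries. They change only how the other libraries enter the fit, and are no check on the sets here. With only both groups in the fit, 270 components were called, of which 100 were higher. The count of 837 fell to 33 without 0 h replicate 2, 333 without 0 h replicate 3, 300 without 6 h replicate 2, 200 without 6 h replicate 3 and 173 without 6 h replicate 4, and it rose to 1568 without 6 h replicate 1. With the close pairs taken as 1 library each it was 159, of which 97 were higher. More components were lower than higher in the 36-library fit, but 58.7%, 56.5% and 58.4% were higher without 6 h replicates 2, 3 and 4, 52% without 0 h replicate 1 and 51% with DESeq2, so no lean was established at 6 h.

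At 12 h, 361 components were higher and 453 lower. The higher components took 3.53% ± 0.473 of all counts at 12 h (SD, n = 4) against 1.06% ± 0.112 at 0 h (SD, n = 3), with a median log2 fold change of 1.89 (median SE 0.43). The lower components took 0.767% ± 0.109 against 3.27% ± 1.39, with a median log2 fold change of -2.14 (median SE 0.50). Calls at both 6 h and 12 h numbered 127 higher and 135 lower, where independent lists of these lengths would share 3.21 and 4.73. Both comparisons use the same 3 libraries at 0 h, and the correlation of fold changes across components was 0.55, below the 0.57 of simulated unchanged groups, but 0.74 against 0.53 in the larger set alone and 0.65 against 0.58 with the set as a term. The numbers called at both times were 162 higher and 234 lower in the larger set alone, and 161 and 210 with the set as a term. At 12 h there were 794 components in the larger set alone, of which 470 were among the 814, and 983 with the set as a term, of which 780 were. The count fell to 33 without 0 h replicate 2, 159 without 0 h replicate 3, and 396, 387, 386 and 374 without 12 h replicates 1, 2, 3 and 4. It rose to 1164 without 0 h replicate 1. The share of higher calls, 44.4% in the 36-library fit, was 57.1% without 12 h replicate 1, 52.1% without 12 h replicate 3 and 23.3% without 0 h replicate 3, so no lean was established at 12 h.

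**Figure D2:**
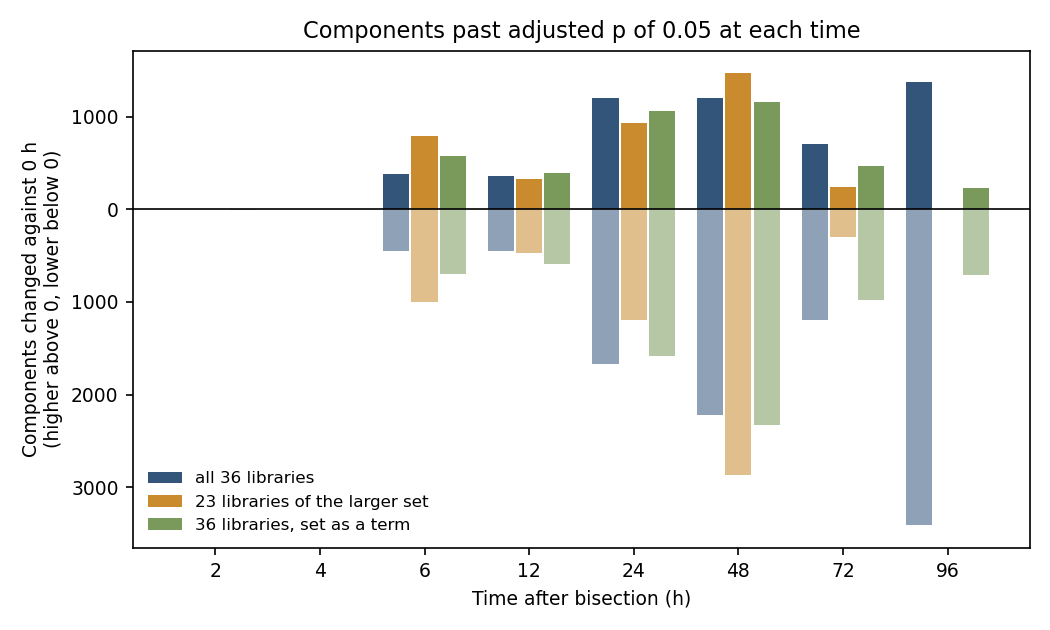
Number of components past a Benjamini-Hochberg adjusted p of 0.05 (edgeR quasi-likelihood test) at each time after bisection (h), with components higher than at 0 h drawn above 0 in full colour and lower ones below 0 in pale colour. Bars stand for all 36 libraries, the 23 libraries of the larger set (no 96 h library) and the 36 libraries with the set as a term. The 36-library fit rises from 0 calls at 2 h and 4 h to 4792 at 96 h, and with the set as a term 948 are called at 96 h.

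In the 36-library fit the counts at 24 h and later exceeded those at 6 h and 12 h, and more components were lower than higher. This order did not hold for every setting, since the larger set alone gave 1789 components at 6 h and 536 at 72 h, and the set as a term gave 1280 at 6 h and 948 at 96 h. At 24 h, 1207 components were higher and 1670 lower, and at 48 h, 1202 were higher and 2223 lower. The components lower at 48 h took 13.7% ± 2.3 of all counts at 0 h (SD, n = 3) and 3.58% ± 0.612 at 48 h (SD, n = 5), with a median log2 fold change of -2.54 (median SE 0.63). The components higher at 48 h took 2.26% ± 0.175 at 0 h and 8.17% ± 1.15 at 48 h, with a median log2 fold change of 1.75 (median SE 0.46). At 24 h the components called higher took 9.04% ± 1.04 (SD, n = 5) against 2.49% ± 0.161 at 0 h, and those called lower took 1.61% ± 0.171 against 6.91% ± 3.34. Within the larger set there were 2132 components at 24 h, of which 1563 were among the 2877, and 4338 at 48 h, of which 2560 were among the 3425. With the set as a term the counts were 2646 and 3491. Without 0 h replicate 2 the counts fell to 595 and 994, without 0 h replicate 3 to 696 and 1598, and without 48 h replicate 4 the 48 h count was 2219. Without 0 h replicate 1 they were 3169 at 24 h and 3043 at 48 h.

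At 72 h, 709 components were higher and 1198 lower. The lower components took 1.03% ± 0.133 of all counts at 72 h (SD, n = 4) against 6.03% ± 1.97 at 0 h (SD, n = 3), with a median log2 fold change of -2.84 (median SE 0.70). The higher components took 5.99% ± 0.969 against 1.77% ± 0.0586, with a median log2 fold change of 2.08 (median SE 0.51). The larger set, with only 2 libraries at 72 h, gave 536 components, of which 418 were among the 1907, and the set as a term gave 1448. The count fell to 303 without 0 h replicate 2, 743 without 0 h replicate 3, 621 without 72 h replicate 1, 999 without 72 h replicate 2 and 1141 without 72 h replicate 3. Without 72 h replicate 4, 54.1% of 1330 calls were higher, so the lean toward lower expression at 72 h rested on that library.

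At 96 h, 1379 components were higher and 3413 lower, so that 28.8% of the 4792 calls were higher. The lower components held 26.7% ± 1.39 of all counts at 0 h (SD, n = 3) and 5.89% ± 2.32 at 96 h (SD, n = 4), with a median log2 fold change of -3.11 (median SE 0.83). The higher components took 1.19% ± 0.118 at 0 h and 4.41% ± 0.776 at 96 h, with a median log2 fold change of 1.85 (median SE 0.50). Changes of 4-fold or more made up 3191 of the calls, and 66 called components had no count in any 0 h library. All 96 h libraries belong to the smaller set and all 0 h libraries to the larger set, and with the set as a term 948 components were called, 236 of them higher, including 801 of the 4792. With the close pairs taken as 1 library each, 1958 components were called at 96 h, of which 595 were higher. The count fell to 2108 without 0 h replicate 2, 2126 without 0 h replicate 3, 2058 without 96 h replicate 1, 2223 without 96 h replicate 2 and 2779 without 96 h replicate 4. The share of higher calls was 45.6% with voom and sample quality weights and 40.3% without the filter on low counts.

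The calls at consecutive late times overlapped. At both 24 h and 48 h, 673 components were higher and 1059 lower, where independent lists would share 33.5 and 85.8. At both 48 h and 72 h there were 457 higher and 952 lower (19.7 and 61.6 for independent lists), and at both 72 h and 96 h there were 422 higher and 789 lower (22.6 and 94.5). Components called at 24, 48, 72 and 96 h in the same direction numbered 209 higher and 462 lower, and 51 were higher and 59 lower at every time from 6 to 96 h. With the set as a term, 612 were higher and 1012 lower at both 24 h and 48 h, 335 and 816 at both 48 h and 72 h, 123 and 333 at both 72 h and 96 h, 64 and 208 at all 4 times from 24 h, and 22 and 56 at every time from 6 to 96 h. In the larger set alone, which ends at 72 h, 539 were higher and 816 lower at both 24 h and 48 h, 182 and 265 at both 48 h and 72 h, and 44 and 55 at every time from 6 to 72 h, where the 36-library fit gave 79 and 72. These comparisons share the 3 libraries at 0 h, which cannot be split so that each part keeps 2, and part of the excess may come from them. In 8 simulations of unchanged groups that share a simulated 0 h group, no comparison called more than 1 component. Each component was drawn on its own there, so traits of the real 0 h libraries are absent. The simulations therefore do not show that those libraries add nothing to the overlap. Across components, which are not independent replicates, the correlation of fold changes was 0.41 between 2 h and 4 h against 0.53 in the simulations, and 0.83 between 72 h and 96 h against 0.59. The covariance exceeded the simulated covariance by 0.0225 between 2 h and 4 h, 0.236 between 6 h and 12 h, 1.07 between 24 h and 48 h and 2.14 between 72 h and 96 h, and it lay below it between 4 h and 6 h, with a difference of -0.0296. These simulations hold a shared simulated 0 h group and no difference between the sets. The smaller set has 0 of 4 libraries at 6 h, 4 of 4 at 96 h and none at 0 h. A difference between the sets would therefore add to the late covariances. Simulated within each setting, the excess between 2 h and 4 h was 0.102 in the larger set alone and -0.058 with the set as a term, where r was 0.31 against 0.55 in the simulations. Between 4 h and 6 h it was 0.304 in the larger set alone and 0.198 with the set as a term, between 24 h and 48 h it was 1.13 and 0.813, and between 72 h and 96 h, where the larger set gives no value, it was 0.841 with the set as a term.

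The late phase was also compared with the early phase directly, as the mean of 48, 72 and 96 h against the mean of 2, 4 and 6 h. In this comparison 4434 components were higher late and 5539 lower late (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the components higher late, 4184 had a late mean above 0 h and 250 a late mean below it. Of those lower late, 5338 had a late mean below 0 h. The components lower late had a median log2 fold change against 0 h of -0.02 early and -1.57 late, and those higher late had -0.08 early and 0.84 late. The components were chosen by this comparison on the same libraries, so the gap between early and late medians follows from the choice, as does part of the lean of late means to the called side of 0 h, and neither is separate evidence. Within the larger set, where the late group held 48 h and 72 h only, there were 5730 components, of which 4510 were among the 9973, and the set as a term gave 6329. Without 4 h replicate 2 the count was 6348. Late against early also follows the sets in part. The smaller set held 2 of 5 libraries at 48 h, 2 of 4 at 72 h and 4 of 4 at 96 h. It held 1 of 4 at 2 h, 1 of 3 at 4 h and 0 of 4 at 6 h.

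Within the larger set, likeness to 0 h tissue fell with time over all libraries, though not from each time to the next. The median Spearman correlation of a library with the 0 h libraries was 0.882 ± 0.0184 at 2 h (SD, n = 3), 0.893 ± 0.00378 at 4 h (SD, n = 2), 0.841 ± 0.0292 at 6 h (SD, n = 4), 0.856 ± 0.00679 at 12 h (SD, n = 3), 0.837 ± 0.02 at 24 h (SD, n = 3), 0.817 ± 0.0209 at 48 h (SD, n = 3) and 0.842 ± 0.00633 at 72 h (SD, n = 2) in this set. Over its 20 libraries after 0 h, this correlation fell with time (Pearson's r = -0.508, permutation p = 0.022, adjusted p = 0.044; Spearman's rho = -0.691, permutation p = 0.00121, adjusted p = 0.00242; two-sided, 2 relations tested). Without the 2 libraries at 72 h, which lie farthest from the median time, r was -0.654. Over the 13 libraries of the smaller set r was -0.532 (permutation p = 0.0635, adjusted p = 0.0635) and rho was -0.518 (permutation p = 0.0734, adjusted p = 0.0734), which did not pass the threshold, and the 4 libraries at 96 h lie equally far from the median time, so that r ranged from -0.894 to -0.353 over the 6 choices of 2 of them to leave out. In the smaller set the single 2 h library had 0.753 and the 4 libraries at 96 h had 0.726 ± 0.0291 (SD). The relation was examined after the sets had been seen, and the sets were made from these same correlations. The permutation tests took each library as a separate sample, and the 3 close pairs were not merged for them.

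**Figure D3:**
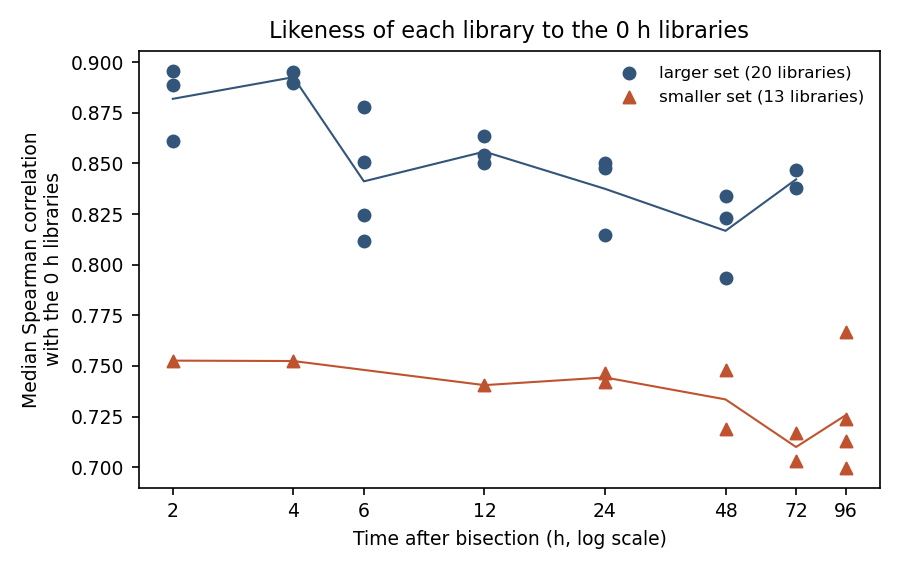
Median Spearman correlation of each library with the 3 libraries at 0 h (vertical axis) against time after bisection (h, log scale), with circles for the 20 later libraries of the larger set, triangles for the 13 of the smaller set and lines through the mean at each time. In the larger set the mean goes from 0.882 at 2 h to 0.817 at 48 h and 0.842 at 72 h, with means at 4, 12 and 72 h above those just before, and the smaller set lies lower at every time that has libraries of both sets.

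By the rule fixed before the data were examined, the components with the largest rises and falls over the joint test are named by number, since no gene names were matched to them. comp267567_c1 had no count in the 3 libraries at 0 h and 50.5 ± 20.1 CPM, the count scaled to a common library size, at 96 h (SD, n = 4), with 36.7 CPM or more in each 96 h library. This is at least 336-fold higher than the floor of 3 counts over the 0 h libraries. Its fitted log2 fold change was 11.45 (SE 3.46, adjusted p = 0.0325 by edgeR). Before 96 h it exceeded 10 CPM only in libraries of the smaller set, though not in all of them. Among them were 4 h replicate 3 at 15.4 CPM, 12 h replicate 4 at 46 CPM, 48 h replicate 3 at 32.8 CPM and 72 h replicate 1 at 39.8 CPM. It had no count in 2 h replicate 4 of that set, and 1.11, 0.141 and 0.136 CPM in 24 h replicates 1 and 4 and 48 h replicate 1. With the set as a term its log2 fold change was 5.03 (adjusted p = 0.286). The call was also lost with a fitted log2 fold change that hardly moved, from 11.12 to 11.58, when a library was left out: the adjusted p was 0.0857, 0.106 and 0.107 without 0 h replicates 1, 2 and 3, and 0.0545, 0.0527 and 0.0549 without 96 h replicates 1, 2 and 4. With the close pairs taken as 1 library each the log2 fold change was 11.68 (adjusted p = 0.0638).

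comp275752_c0 was absent from the 0 h counts and reached 47.9 ± 95.4 CPM at 96 h (SD, n = 4), at least 318-fold above the floor of 3 counts over the 0 h libraries. This value came from 96 h replicate 3 at 191 CPM, and the next 96 h library had 0.453 CPM. Its fitted log2 fold change was 11.37 (SE 3.42, adjusted p = 0.0333 by edgeR), and without 96 h replicate 3 it was 3.53 (adjusted p = 0.454). Without 0 h replicates 1, 2 and 3 the adjusted p was 0.0864, 0.106 and 0.106, while the log2 fold change stayed between 11.37 and 11.38. With the set as a term the log2 fold change was 6.94 (adjusted p = 0.455).

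comp242432_c0 and comp231327_c0 were the largest falls. comp242432_c0 went from 60.3 ± 54.7 CPM at 0 h (SD, n = 3) to no count in the 5 libraries at 48 h, which is at least 695-fold lower than at 0 h with a floor of 3 counts over the 48 h libraries. Its fitted log2 fold change was -11.71 (SE 2.02, adjusted p = 0.00116 by edgeR). comp231327_c0 went from 41.1 ± 36.7 CPM at 0 h (SD, n = 3) to no count in the 4 libraries at 6 h, at least 322-fold lower, with a fitted log2 fold change of -11.15 (SE 2.00, adjusted p = 0.00576 by edgeR). Neither component had a count in 0 h replicate 1. comp242432_c0 did not fall steadily. It had 0.142 ± 0.096 CPM at 2 h (SD, n = 4), where it was not called (adjusted p = 0.124 by edgeR). At 6 h it had 0.0804 ± 0.0928 CPM (SD, n = 4) and was called lower (adjusted p = 0.0128 by edgeR). It had 15 ± 15.1 CPM at 4 h (SD, n = 3) and 8.65 ± 10.3 CPM at 12 h (SD, n = 4). It passed the test at neither of these times (at 12 h, adjusted p = 0.269 by edgeR). Its 4 h replicates 2, 3 and 4 had 0.151, 30.3 and 14.6 CPM. comp231327_c0 had 1.58 ± 2.18 CPM at 12 h (SD, n = 4) and was lower there (adjusted p = 0.0476 by edgeR). Both were called lower at 24, 48, 72 and 96 h.

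**Figure D4:**
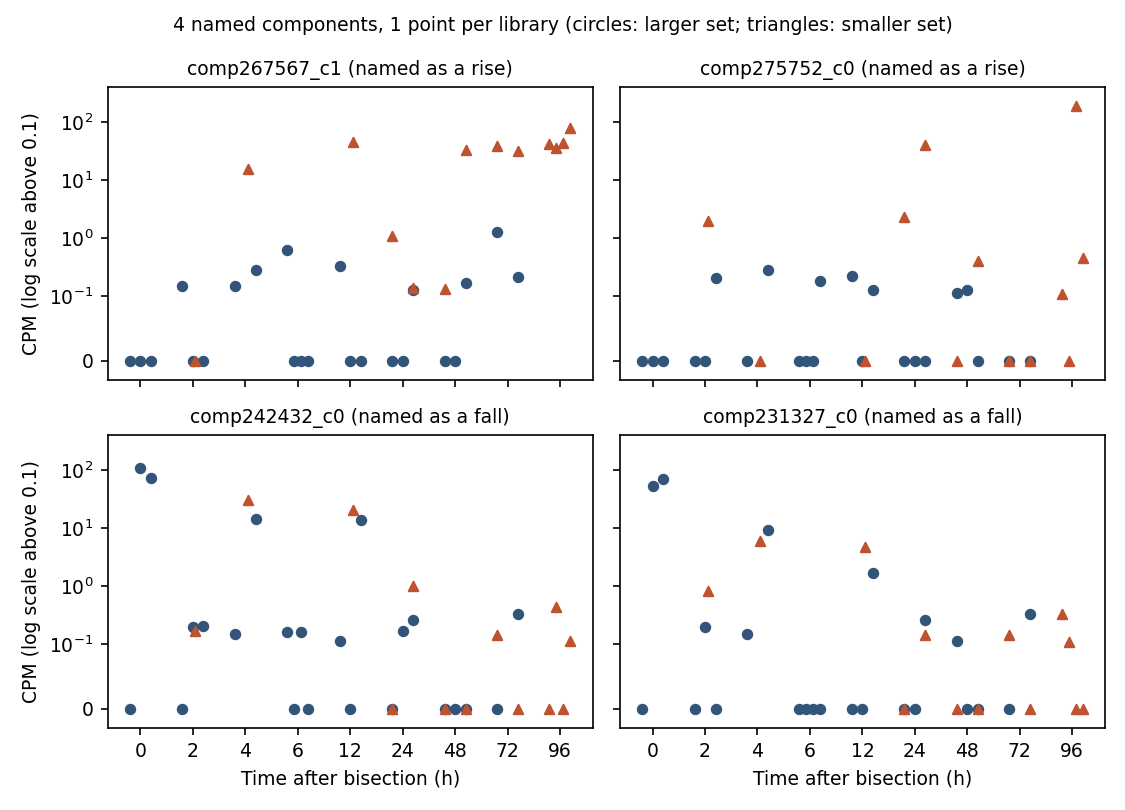
CPM (log scale above 0.1) of the 4 named components in each of the 36 libraries against time after bisection (h), with circles for the larger set and triangles for the smaller set. The components named as rises have no count at 0 h and reach 80.4 and 191 CPM at 96 h, and those named as falls reach 107 and 70.7 CPM at 0 h with no count in 1 of the 3 libraries at 0 h.

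The authors' deposited table, which compares each time with 0 h, was set beside these counts. It lists 976 components below an adjusted p of 0.05 at 6 h, 1094 at 12 h, 2330 at 24 h, 2411 at 48 h, 1987 at 72 h and 5282 at 96 h. Its adjusted p-values cover 160987 components at 6 h and 183030 at 96 h, against 43271 tested here. Of the 5282 listed at 96 h, 4924 were tested here. Components called in both that table and the edgeR test numbered 395, 493, 1696, 1879, 1235 and 3260 at these times. Each had the same direction in both, which is not separate evidence, since both come from the same libraries. In the authors' deposited table the components listed as higher were 1750 of 5282 at 96 h and 518 of 976 at 6 h.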

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

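The tests of time as the only cause of the sets, of copies under a shared component number, of the set as a term and of the smaller set's spread were chosen only after the results were seen; the tests of depth, of library number and of other splits were set beforehand.

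Single libraries stood far from the rest of their time for the named components, by Dixon's test in groups of 4 or 5 libraries, in 12 of 25 groups tested. The test passes a share of about 0.05 of groups by chance where values are evenly spread, but these components were chosen for extreme changes and are mostly at 0, where a lone library with counts is always singled out, so the excess carries no weight. None of 21 groups tested for the total count, the number of detected components or the share of the most abundant component had such a library. For comp267567_c1 the CPM was 0.151 in 2 h replicate 1, 0.639 in 6 h replicate 1, 46 in 12 h replicate 4, 1.11 in 24 h replicate 1, 32.8 in 48 h replicate 3 and 80.4 in 96 h replicate 4. For comp275752_c0 it was 2.01 in 2 h replicate 4, 0.187 in 6 h replicate 4, 41.2 in 24 h replicate 4 and 191 in 96 h replicate 3. For comp242432_c0 it was 0.99 in 24 h replicate 4, and for comp231327_c0 it was 0.113 in 48 h replicate 2. The values of 0.113, 0.151 and 0.187 CPM each come from 1 count. A different change late and early was found for 9973 components by the test of that difference.

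The split of the libraries into 2 sets ran along the first principal component of the data. Depth was argued against, since 0 libraries changed set when all were thinned to the smallest total. Time as the only cause was argued against, since 6 of 9 times had libraries in both sets and 0 libraries differed in set between sets made from 21649 components and from the other 21622, though time may still contribute. Copies of a gene may take reads in turn under a shared component number. Of 3268 pairs of components with a shared number, 1.41% had a residual correlation under -0.5, against 3.24% of random pairs. The median residual correlation was 0.329 for pairs with a shared number and -0.00132 for random pairs. This argues against copies taking reads in turn in most such pairs, but the comparison could miss a minority of them. Copies assembled under different numbers were not examined. Holding site, extraction kit, genetic background and the state of the worms are also open and untested, since the labels do not assign them to samples.

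The highest count at a single time, 4792, was at 96 h, where time and set coincide for the 0 h and 96 h libraries; with the 3 close pairs of libraries taken as 1 library each it was 1958 at 96 h and 3182 at 48 h. With the set as a term, whose size rests on the 9 libraries of the smaller set from 2 to 72 h, 948 components were called instead of 4792. Over all 4792 components the median absolute log2 fold change went from 2.68 (median SE 0.71) to 1.84 (median SE 0.72), and over all 43271 tested it went from 0.74 (median SE 0.58) to 0.61 (median SE 0.63). The sets were found in the same expression values and the 96 h libraries helped to define them, so a smaller estimate was partly built in. How much of the 96 h count belongs to the set and how much to a continued response to the cut cannot be told apart, because all 0 h libraries lie in the larger set and all 96 h libraries in the smaller.

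No component was called at 2 h or at 4 h by edgeR in all 36 libraries after the filter on low counts. Without the smaller-set libraries 0 components were called at these times. This cannot decide whether their spread was the reason, since only 3 libraries were then left at 2 h and 2 at 4 h. The biological coefficient of variation was 0.412 in the larger set against 0.564 in all libraries. The larger set was made from libraries that resemble each other, so a lower value there is partly built in. With the set as a term, which keeps all 36 libraries and takes out a shift common to the smaller set, 1 component was called at 2 h and 0 at 4 h. Spread within the smaller set stays open. At least 49.3% of simulated 8-fold changes were recovered at both times, but few 2-fold changes were. Each component was drawn on its own there, without the sets or shifts shared by many components. This argues against too few libraries to call any large change only as far as the real libraries behave like the simulated ones. Small early changes stay open, as do the filter, without which edgeR called 1463 and 1133 components, and the choice of test, with which DESeq2 called 226 and 166.

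Other splits of the samples, with each library taken as a separate sample, were refitted for each comparison, up to 80 of them. Over all times, 1 of 80 splits, the real one, gave as many as 10237 components, and the highest other gave 1039. The real split also gave the most calls at 12 h (814 against 37 in the highest other of 35 splits), 24 h (2877 against 435, 56 splits) and 48 h (3425 against 504, 56 splits). The same held at 72 h (1907 against 137, 35 splits), 96 h (4792 against 2685, 35 splits) and late against early (9973 against 2808, 80 splits). In each of these, as over all times, the count of splits as large was 1, which argues against chance. Chance is not excluded, since 35 splits can give no share below 1 of 35. The comparisons were also not adjusted for their number. The close pairs were not merged here, and at 96 h the real split is also the split by set. Late against early, the real split follows the sets in part. At 6 h the splits do not argue against chance, since 2 of 35 gave as many calls. The split that set 6 h replicates 2, 3 and 4 against the 0 h libraries with 6 h replicate 1 gave 1210 against 837. That split points to structure among the 6 h replicates. The highest other split at 96 h set 96 h replicates 1, 2 and 4 against the 0 h libraries with 96 h replicate 3. It keeps most of the difference between 0 h and 96 h and gave fewer calls than the real split, so nothing about structure follows from it. At 2 h and 4 h the real value was 0, which all 35 and all 10 splits reach by construction, so nothing about chance follows; the highest other values were 317 and 191.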

How the results depend on the processing

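The larger set alone, the set as a term and close pairs taken as 1 library were chosen after the data were seen. The cause of each shift below was not tested. Fits without a library have fewer samples, but that alone does not set the count. At 12 h it was 1164 without 0 h replicate 1 and 33 without 0 h replicate 2. Counts stayed within 1.5 times of those given for all comparisons with RLE size factors, the stricter filter and rows of a component number summed. With limma voom and sample quality weights the counts were 30483 at any time, 1355, 419, 7951, 7145, 8968, 10689, 6307 and 19026 at 2, 4, 6, 12, 24, 48, 72 and 96 h, and 16670 late against early. Without the filter on low counts they were 23904 at any time and 1463, 1133, 1900, 2633, 4605, 5601, 4707 and 9119 at these times. DESeq2 gave 226 at 2 h, 166 at 4 h, 2267 at 6 h, 1983 at 12 h, 4403 at 24 h and 3261 at 72 h. With only both groups in the fit there were 3 at 2 h, 270 at 6 h, 286 at 12 h and 2046 at 48 h. The larger set alone gave 4959 at any time, 1789 at 6 h, 536 at 72 h and 5730 late against early. The set as a term gave 1 at 2 h, 1280 at 6 h, 948 at 96 h and 6329 late against early. With the 3 close pairs taken as 1 library each, there were 6317 at any time, 159 at 6 h, of which 61% were higher against 46% with all libraries, and 1958 at 96 h. A log2 fold change of at least 1 left 5961 late against early, of which 33.6% were higher against 44.5% without that minimum. The other counts under these settings were within 1.5 times of those given. DESeq2 put the log2 fold change of comp267567_c1 at 22.09 (adjusted p = 6.06e-12) against 11.45 by edgeR, both fitted against a group with no counts and neither a bound, and it gave no adjusted p for comp275752_c0.

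Without each library in turn the counts ranged from 8099 to 11359 at any time, 0 to 24 at 2 h, 0 to 42 at 4 h, 33 to 1568 at 6 h, 33 to 1164 at 12 h, 595 to 3183 at 24 h, 994 to 3804 at 48 h, 303 to 2170 at 72 h, 2058 to 5327 at 96 h and 6348 to 11889 late against early. The lowest counts from 6 h to 72 h were those without 0 h replicate 2. The share of higher calls moved by over 10 points without 0 h replicate 2 (27.3% at 6 h, 33.3% at 12 h, 29.4% at 24 h, 19.5% at 48 h, 21.5% at 72 h and 17.3% at 96 h), without 0 h replicate 3 (23.7% at 6 h, 23.3% at 12 h, 22.4% at 48 h and 22.1% at 72 h), without 6 h replicates 2, 3 and 4 (58.7%, 56.5% and 58.4% at 6 h), without 12 h replicate 1 (57.1% at 12 h) and without 72 h replicate 4 (54.1% at 72 h). The falls of comp242432_c0 and comp231327_c0 kept their calls under every setting in which they were followed. They were not followed with voom, without the filter, with the stricter filter, with components summed or with only both groups in the fit. When a library of 0 h or of their own time was left out, their log2 fold changes ran from -12.30 to -11.00 and from -11.74 to -10.48.

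The replicate numbers did not pair the samples: over 129 pairs with the same number in the titles the median correlation of deviations from the time means was 0.0245, 37.2% of pairs were over 0.1, and 10 of 36 libraries correlated best with their own number. With the numbers of the sample names, which differ at 0 h, 39.5% of pairs were over 0.1. With the replicate block by title the counts were 8749 at any time, 1 at 2 h, 0 at 4 h, 757 at 6 h, 554 at 12 h, 2354 at 24 h, 2939 at 48 h, 1600 at 72 h, 4117 at 96 h and 9698 late against early, and comp275752_c0 no longer passed (adjusted p = 0.066). With the replicate block by sample name they were 9449 at any time, 0, 0, 786, 1115, 3879, 4147, 2628 and 6216 at 2, 4, 6, 12, 24, 48, 72 and 96 h, and 9748 late against early, and comp275752_c0 passed (adjusted p = 0.0199). Gene list tests were planned and not run, because no gene names were matched. The simulated data had the depth of these libraries and the spread of each component, but no sets. There, edgeR recovered at most 5% of 2-fold changes at any time and from 20.3% (96 h) to 43.6% (24 h) of 4-fold changes.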

Other observations

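The descriptions in this part were chosen after the data were seen, and no tests were run for them. Among the 10237 components that passed the joint test, the time with the largest absolute fold change against 0 h was 96 h for 31.8%, 24 h for 17.2%, 48 h for 14%, 6 h for 11.1%, 72 h for 10.1%, 12 h for 7.16%, 2 h for 6.44% and 4 h for 2.33%. At 24 h 937 of these peaked as higher and 820 as lower, and at 96 h 1393 as higher and 1857 as lower. A group with more spread or fewer libraries has a larger chance of holding the extreme, so these shares are a description of the estimates and not a count of responses.

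Components that fell had been more abundant at 0 h than those that rose. At 48 h the median 0 h level was 13 CPM for the 2223 components called lower and 4.49 CPM for the 1202 called higher, and at 96 h it was 9.19 CPM and 2.3 CPM. At 96 h the median level was 1.11 CPM for the components called lower and 10.8 CPM for those called higher. These levels are those of components chosen by the test, and no test of the difference in level was run.

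The nearest library by Spearman correlation was from another time for 12 of the 23 libraries of the larger set and 10 of the 13 of the smaller set. In the larger set, the nearest library of 12 h replicate 1 was 48 h replicate 2 (0.946) and that of 24 h replicate 3 was 6 h replicate 3 (0.929). In the smaller set, the nearest library of 4 h replicate 3 was 96 h replicate 1 (0.914), that of 12 h replicate 4 was 96 h replicate 4 (0.912), that of 72 h replicate 1 was 96 h replicate 4 (0.908) and that of 72 h replicate 2 was 96 h replicate 2 (0.919). The nearest library of 2 h replicate 4 was 24 h replicate 4 (0.844), that of 24 h replicate 1 was 48 h replicate 3 (0.847), and that of 48 h replicate 1 was 48 h replicate 2 of the larger set (0.822).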
